A study of Mus musculus with 20 samples.

How the data were processed

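The samples were 20 libraries of tdTomato-sorted AgRP neurons, 5 in each of 4 groups (wild type or Phf6 cKO, fed or fasted), made with a SMART-seq v4 kit after 15 cycles of cDNA amplification and a Nextera XT kit, per the labels' protocols. Neither kit marks the strand of a transcript. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to the GRCm38 (mm10) mouse genome with HISAT2 2.1.0, counted per gene with featureCounts of Subread 1.6.2 and normalized with DESeq2 1.20.0. The gene annotation and the strand setting of the counting are not given in the sources used here.

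The deposited count table holds raw read counts for 23129 named genes in 20 libraries, of which 3897 have no count in any library. The deposited normalized table holds a normalized signal, which is each count divided by 1 size factor per library. The ratio of both tables was constant within each library to a relative deviation of 6.29e-10, and it equalled a median-of-ratios size factor computed here to 2.16e-11. Of the names, 22063 (95.4%) matched gene symbols of GENCODE M21 on GRCm38, from which coordinates, lengths and overlaps were taken. A further 27 names had been turned into dates, of which 2 occur more than once, and they were left unnamed. Mitochondrially encoded genes are absent from the table. The counting rules for shared reads are not given, so exon overlaps are stated for the named genes that share more than 10% of their exon bases with another gene. Smaller overlaps are not marked at each gene and were largest for Cox4i1 (9.9%), Nr1d1 (8.5%), Cdkn1a (7.7%), Junb (7.5%), Jun, Nudt12 and Rps2 (7.3% each).

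Depth ran from 8494499 to 13573524 counts per library. A count of 0 allows up to 3 counts, or 0.221 to 0.353 CPM depending on the library, and this covers counting error only, since amplified reads without molecular identifiers are not independent molecules.

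Genes were tested with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M values (TMM) normalization, the edgeR filter on low counts (minimum count 10, minimum total 15), a model of 4 group means over all 20 libraries and the quasi-likelihood test. The filter left 13237 genes with at least 99.9% of each library's counts. The 5 comparisons were fasting in wild type, fasting in cKO, cKO against wild type in fed mice, the same in fasted mice, and the interaction of genotype with fasting, and 2 averages were added. P-values were adjusted by the Benjamini-Hochberg method within each comparison over all tested genes, and a gene was said to rise or fall at an adjusted p under 0.05. Log2 fold changes are given ± SE and CPM, which use TMM, as mean ± SD with n = 5.

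Gene lists of 39 pathways and cell types were written from general knowledge before the data were examined, as were the groups, the comparisons, the rule for naming genes and the alternatives to each processing choice. Of 945 list members, 18 were not in the table. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and adjusted over the 33 tested lists, of which 25 were pathways and 8 cell types. Camera, of limma, asks whether a list's members changed more than other genes, and a list's median is the median log2 fold change of its tested members. Camera was repeated with an estimated correlation, and each list was also counted with p-values adjusted over the list alone. The fry test was run beside it and compares no list with other genes. List scores, the mean log2 CPM of a list in each library, were compared by 2-sided exact permutation tests, for which 5 against 5 libraries can give no p below 0.00794. Lists of mitochondrially encoded genes, kisspeptin (KNDy) neurons, oligodendrocyte precursors, microglia and macrophages, erythrocytes and pituitary tissue had 0 or 1 tested member and were not tested.

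The genes open to naming were Phf6, Agrp and Npy, then per comparison the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean log2 CPM of at least 2 and all 5 values of a group on 1 side of the other group's mean. For the interaction and the averages the 10 smallest p-values were used. Up to 4 members of each list with the smallest p past the threshold were added. Numbered gene models, Y-linked genes and X-inactivation genes were left out of this rule. The genes in the text are a subset of these, picked after the values were seen, and they form 154 pairs of gene and comparison besides Phf6.

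Before use, the steps were tested on simulated counts with 200 changed genes. The test recovered 51%, 59%, 55% and 55% of 1.5-fold changes and 80%, 78%, 77% and 77% of 2-fold changes for fasting in wild type (13058 genes), fasting in cKO (13069), cKO in fed mice (13068) and cKO in fasted mice (13059). Unchanged genes were 4%, 2%, 6.5% and 6.5% of the calls.

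The alternatives set then were DESeq2 size factors, upper-quartile normalization, no filter, a filter at 1 CPM in 5 libraries, a robust fit, a term for replicate number, fits of only the groups compared, the DESeq2 1.42.0 test, limma-voom 3.58.1 with quality weights, limma on the deposited normalized values (log2 after adding 1), leaving out each library, other list tests, other gene choices for the slope and the 10 most abundant genes. A term for sex was not run because all libraries held transcripts of the same sex. After seeing the data 5 more were added, namely fasted replicates 1 and 2 only, fasted replicates 3 to 5 only, a term for the library sets of the fasted groups, summed counts of each set, and offsets for GC content and transcript length fitted by loess. The replicate numbers were not used as pairs, because deviations of libraries with the same number had correlations from -0.054 to 0.13 with a median of 0.002. The 5 pairs of fasted wild type with fasted cKO were all positive, from 0.022 to 0.13, and the replicate and set terms are the fits that allow for this. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.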

Results

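The data were gene-level RNA counts from AgRP neurons, the hypothalamic neurons that make agouti-related peptide and neuropeptide Y and drive feeding. The neurons carried the red reporter tdTomato and were sorted from hypothalamic tissue of C57BL/6 mice 25 to 30 days old, with 1000 cells per sample, per the labels' protocols. The 20 libraries formed 4 groups of 5, which crossed genotype with feeding state. Wild-type mice carried Cre recombinase under the Agrp gene and the reporter, and conditional knockout (cKO) mice also carried a floxed copy of Phf6, an X-linked gene for a chromatin-binding protein. Fed mice had food throughout, and for fasted mice the food was removed at 5 pm on the day before collection. The comparisons ask how fasting changed the RNA of these neurons and whether loss of Phf6 changed that response. Total counts ran from 10604977 to 13573524 in fed libraries and from 8494499 to 10000278 in fasted libraries. Fasted libraries were shallower in wild type, with 9537653 ± 614360 against 12380890 ± 676360 counts (mean ± SD, n = 5 each), and in cKO, with 8917873 ± 322910 against 12347381 ± 1467000 (2-sided exact permutation p = 0.00794 each, adjusted p = 0.00952). Between 15063 and 15917 genes had at least 1 count per library. Every library held at least 205 counts of each Y-linked gene read and at most 9 of Xist, so all 20 came from males by this measure. The labels do not state whether each replicate was a separate mouse, so errors and p-values describe the spread between samples.

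Phf6, the targeted gene (chromosome X, 52912266 to 52956943, plus strand, GRCm38), separated the genotypes in every library. Its level was 276 ± 10.2 CPM (library-scaled counts, mean ± SD, n = 5) in fed wild type, 128 ± 11 in fasted wild type, 70.7 ± 4.85 in fed cKO and 61.2 ± 6.9 in fasted cKO. Single libraries ranged from 264 to 292 CPM in fed wild type, 116 to 143 in fasted wild type, 65.0 to 76.3 in fed cKO and 53.6 to 71.3 in fasted cKO. The fall with cKO was 3.91-fold in fed libraries (log2 fold change -1.97 ± 0.072 SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 4.02e-18) and 2.09-fold in fasted libraries (-1.07 ± 0.074, edgeR adjusted p = 2.43e-10). Fasting itself lowered Phf6 2.16-fold in wild type (-1.11 ± 0.070, edgeR adjusted p = 1.42e-13) and 1.15-fold in cKO (-0.21 ± 0.074, edgeR adjusted p = 0.0199). The small fall in cKO no longer passed without cKO_fed replicate 1 or 4 or cKO_fasted replicate 1 or 2 (edgeR adjusted p from 0.0541 to 0.0736). The deleted exons are not given in the sources used here, so counts over the whole gene do not measure how many cells had lost the protein.

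Agrp and Npy, the feeding peptides that define these neurons, were among the most abundant transcripts. Agrp (chromosome 8, 105566698 to 105637393, minus strand) was at 4554 ± 185 CPM in fed wild type, 14930 ± 2487 in fasted wild type, 5066 ± 400 in fed cKO and 11310 ± 1548 in fasted cKO (mean ± SD, n = 5 each). Npy (chromosome 6, 49822710 to 49829507, plus strand) was at 16670 ± 648, 53990 ± 10800, 23470 ± 1471 and 45330 ± 6487 CPM in the same order. Npy alone took 1.82% of counts in fed wild type and 4.92% in fasted wild type, and 2.51% and 4.23% in the cKO groups. The 50 most abundant genes took 13.99 ± 0.067% of counts in fed and 19.7 ± 0.96% in fasted wild type (mean ± SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.00952). In cKO they took 14.9 ± 0.22% and 18.1 ± 0.72% (exact permutation p = 0.00794, adjusted p = 0.00952), and the fed genotypes differed as well (exact permutation p = 0.00794, adjusted p = 0.0159). Of the annotated exon bases of Agrp, 11.3% are shared with Ctcf on the opposite strand, and the library kit did not mark strand, so a small part of its counts is uncertain.

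**Figure D1:**
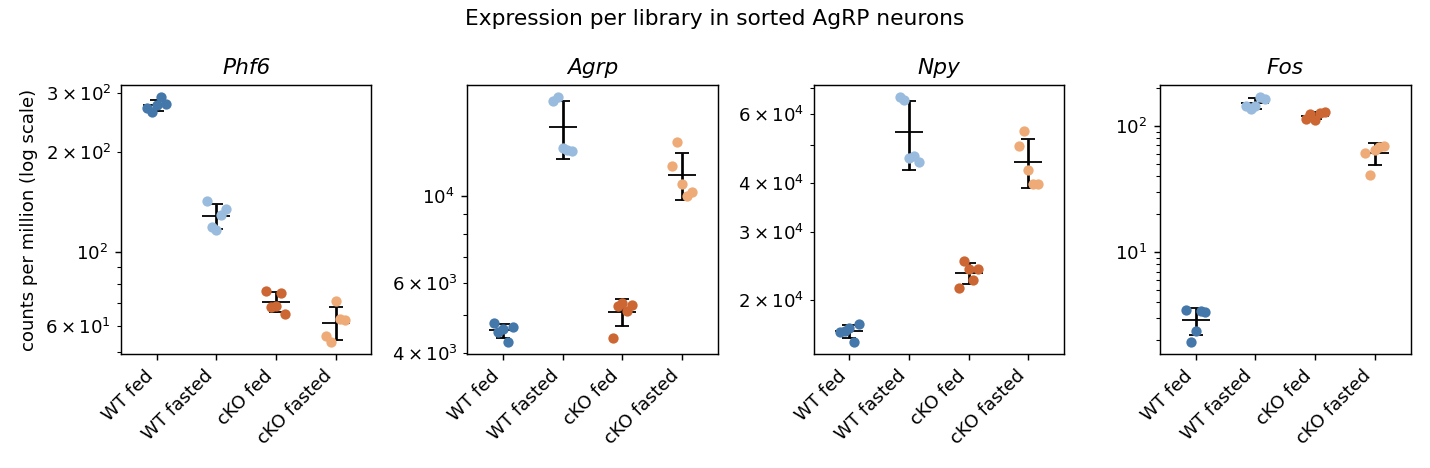
CPM of Phf6, Agrp, Npy and Fos on a log axis, with 1 point per library and the mean ± SD of 5 libraries for each of the 4 groups. Phf6 was lower in every cKO library than in every wild-type library, and Fos was near 2.91 CPM in fed wild type and above that in every other library.

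The largest axis of variation between libraries was feeding state. The first principal component held 48.7% of the variance of the tested genes and separated fed from fasted libraries, the second held 9% and the third 5.8%. Within each fasted group, replicates 1 and 2 stood apart from replicates 3 to 5. Mean correlations of deviations from the group mean were 0.043 within and -0.44 between these sets in fasted wild type, and -0.091 and -0.35 in fasted cKO. The fed groups had no such sets (-0.25 within and between in wild type, -0.25 and -0.25 in cKO). The biological coefficient of variation was 0.178 over the 5 fasted wild-type libraries, against 0.102 and 0.0991 within its sets, and 0.142 against 0.112 and 0.099 in fasted cKO. In fed groups it was 0.0789 and 0.0931. In fasted wild type the sets also differed in markers of other cell types, as the astrocyte list had mean log2 CPM of 2.61 and 2.45 in replicates 1 and 2 against 1.09, 0.38 and 0.61, and the tanycyte list 1.68 and 1.39 against 0.10, -0.63 and -0.51. In fasted cKO these lists did not part the sets. The Pomc neuron list was lower in replicates 1 and 2 of both genotypes, with 6.15 and 6.05 against 6.63, 6.73 and 6.42 in wild type and 5.96 and 6.23 against 7.22, 7.52 and 7.40 in cKO, as was the endothelial list (1.38 and 1.53 in wild type and 0.31 and 1.13 in cKO, against at least 1.604 and 1.17). The labels give no cause for the sets, and whether libraries of a set share mice or a working day is not stated.

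**Figure D2:**
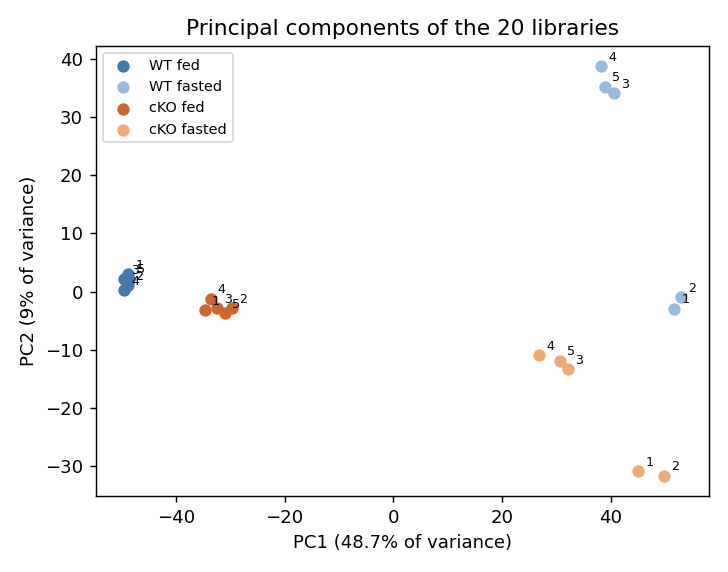
First against second principal component of log2 CPM, with 1 point per library coloured by group and marked with its replicate number. The first component (48.7%) separated fed from fasted libraries, and the second held 9%.

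Fasting of wild-type neurons asks which genes answer to hunger when Phf6 is intact. Agrp rose 3.28-fold (log2 fold change 1.71 ± 0.088 SE, 5 against 5 libraries, edgeR adjusted p = 1.79e-15) and Npy rose 3.24-fold (1.7 ± 0.094, edgeR adjusted p = 1.03e-14). The largest rises of clear abundance included Cdkn1a, which encodes the cell-cycle inhibitor p21 and rose from 4.45 ± 0.686 to 316 ± 35.2 CPM (70.6-fold, 6.14 ± 0.12, edgeR adjusted p = 3.91e-25). The activity-induced transcription factors Fos (51.9-fold, 5.7 ± 0.14, edgeR adjusted p = 2.09e-22), Egr1 (60.2-fold, 5.91 ± 0.21, edgeR adjusted p = 1.02e-18) and Nr4a1 (4.96 ± 0.31, edgeR adjusted p = 7.91e-14) rose from under 3 CPM each in fed libraries. The metal-binding metallothioneins Mt1 (4.91 ± 0.18, edgeR adjusted p = 1.57e-18) and Mt2 (5.61 ± 0.27, edgeR adjusted p = 4.3e-16) rose too, with Mt2 uncertain because 73.5% of its exon bases face an antisense model. The neurotensin gene Nts (6.48 ± 0.69, edgeR adjusted p = 3.99e-09) and the lysosomal gene Cd68 (4.72 ± 0.27, edgeR adjusted p = 1.79e-14) rose as well. Among the falls were Tnfaip8l3, a lipid-transfer gene (-3.83 ± 0.24, edgeR adjusted p = 1.39e-13), the neurofilament gene Nefl (-2.99 ± 0.27, edgeR adjusted p = 1.5e-10) and Socs3, which restrains leptin and cytokine signalling (-2.92 ± 0.29, edgeR adjusted p = 8.55e-10). The repressor gene Bhlhe40 (-2.9 ± 0.17, edgeR adjusted p = 2.01e-14) and Mef2c, an activity-dependent transcription factor (-2.76 ± 0.24, edgeR adjusted p = 8.25e-11), fell as well. Of the hormone receptors, Lepr for leptin (2.12 ± 0.14, edgeR adjusted p = 2.46e-13) and Ghsr for ghrelin (1.55 ± 0.11, edgeR adjusted p = 8.08e-13) rose. The inhibitory autoreceptor gene Npy2r fell from 431 ± 11 to 95.8 ± 16 CPM (-2.17 ± 0.081, edgeR adjusted p = 1.82e-18). Nefl shares 32.8% of its exon bases with Nefm on the opposite strand, so its change is uncertain. In all, 3920 of 13237 tested genes rose and 4138 fell, 1049 and 1169 of them by at least 2-fold, and the balance turned to 4053 and 3831 with GC and length offsets.

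Gene groups fixed before the data were examined moved broadly with fasting in wild type, and 15 of 33 tested lists passed camera, 9 upward and 6 downward. Of the immediate early and activity genes, 24 of 34 rose, 5 fell and 5 did not pass (24 and 5 adjusted over the list alone), with Jun among the falls (-1.68 ± 0.091). Their median was 1.28 (camera adjusted p = 6.29e-07, adjusted p = 0.00348 with an estimated correlation). Of the late activity genes, 12 of 17 rose, 2 fell and 3 did not pass (12 and 2 adjusted over the list alone). Their median was 1.22 (camera adjusted p = 6.29e-07, adjusted p = 0.00348 with an estimated correlation). Of the glucocorticoid and FoxO response genes, 17 of 24 rose, 2 fell and 5 did not pass (18 and 2 adjusted over the list alone), led by the kinase gene Sgk1 (2.84 ± 0.075). Their median was 1.41 (camera adjusted p = 6.68e-17, adjusted p = 0.000574 with an estimated correlation). Of the peptide processing and secretory granule genes, 14 of 20 rose, 4 fell and 2 did not pass (14 and 4 adjusted over the list alone), including Vgf (2.38 ± 0.081), Scg2 (1.33 ± 0.071) and the prohormone protease Pcsk1 (1.33 ± 0.081). Their median was 0.5 (camera adjusted p = 4.11e-07, adjusted p = 0.00348 with an estimated correlation). Of the AgRP neuron identity genes, 8 of 14 rose, 2 fell and 4 did not pass (9 and 2 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 0.023, adjusted p = 0.0656 with an estimated correlation). Of the endoplasmic reticulum stress and folding genes, 23 of 38 rose, 4 fell and 11 did not pass (23 and 4 adjusted over the list alone), such as the chaperone genes Dnajb9 (1.49 ± 0.058) and Pdia6 (0.74 ± 0.049). Their median was 0.35 (camera adjusted p = 3.7e-06, adjusted p = 0.0142 with an estimated correlation).

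Lists of ribosomal protein, oxidative phosphorylation and proteasome genes rose with fasting in wild type. Of the cytosolic ribosomal protein genes, 77 of 78 rose, 0 fell and 1 did not pass (77 and 0 adjusted over the list alone), for example Rpl10 (1.2 ± 0.055). Their median was 0.87 (camera adjusted p = 1.16e-48, adjusted p = 0.0546 with an estimated correlation). Their mean rose from 7.67 ± 0.047 to 8.52 ± 0.11 log2 CPM (mean ± SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0125), and near-identical copies leave single ribosomal genes uncertain. Of the nuclear oxidative phosphorylation genes, 60 of 72 rose, 5 fell and 7 did not pass (60 and 5 adjusted over the list alone), such as Ndufa12 of complex I (1.02 ± 0.063) and Cox4i1 of complex IV (0.81 ± 0.055). Their median was 0.57 (camera adjusted p = 1.88e-17, adjusted p = 0.0912 with an estimated correlation). Of the proteasome genes, 26 of 33 rose, 1 fell and 6 did not pass (26 and 2 adjusted over the list alone), with Psmb3 (1.08 ± 0.049) among them. Their median was 0.38 (camera adjusted p = 3.72e-08, adjusted p = 0.0802 with an estimated correlation). With GC and length offsets, an alternative chosen after seeing the data, the ribosomal median was 0.52 ± 0.035 and the oxidative phosphorylation median 0.10 ± 0.046, and both lists still passed.

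Downward with fasting in wild type 6 lists passed. Of the cholesterol synthesis genes, 2 of 24 rose, 18 fell and 4 did not pass (2 and 18 adjusted over the list alone), including Hmgcs1, an early enzyme of the pathway that fell from 181 ± 8.57 to 45.1 ± 8.34 CPM (-2.01 ± 0.098), Sqle (-1.67 ± 0.11) and Fdft1 (-1.36 ± 0.065). Their median was -0.91 (camera adjusted p = 3.03e-08, adjusted p = 0.0142 with an estimated correlation). Of the heat shock genes, 0 of 19 rose, 14 fell and 5 did not pass (1 and 15 adjusted over the list alone), including Hsph1 (-1.76 ± 0.076) and the co-chaperone Stip1 (-1.2 ± 0.053). Their median was -0.54 (camera adjusted p = 5.09e-07, adjusted p = 0.021 with an estimated correlation). Of the cytokine and insulin feedback genes, 3 of 27 rose, 15 fell and 9 did not pass (3 and 15 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.0197, adjusted p = 0.0912 with an estimated correlation). Of the fatty acid oxidation genes, 3 of 23 rose, 12 fell and 8 did not pass (3 and 12 adjusted over the list alone). Their median was -0.31 (camera adjusted p = 0.0391, adjusted p = 0.212 with an estimated correlation). Of the ionotropic glutamate receptor and scaffold genes, 7 of 38 rose, 19 fell and 12 did not pass (7 and 19 adjusted over the list alone). Their median was -0.21 (camera adjusted p = 0.0272, adjusted p = 0.0912 with an estimated correlation). Of the sodium, calcium and HCN channel genes, 7 of 28 rose, 16 fell and 5 did not pass (7 and 16 adjusted over the list alone). Their median was -0.41 (camera adjusted p = 0.0256, adjusted p = 0.15 with an estimated correlation). With GC and length offsets the cytokine list (camera adjusted p = 0.0775), the glutamate list (0.15) and the sodium channel list (0.0817) no longer passed. With fasted replicates 1 and 2 alone the cytokine (camera adjusted p = 0.066), fatty acid oxidation (0.0774), glutamate (0.066) and sodium channel (0.212) lists did not pass, and with replicates 3 to 5 alone the fatty acid oxidation and glutamate lists did not (0.0599 each). Fdft1 shares 18.3% of its exon bases with Ctsb on the opposite strand and Hmgcs1 12.1% with an antisense model.

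The other 10 pathway lists did not pass in wild type. These were glycolysis (2 rose and 11 fell of 20, camera adjusted p = 0.0525) and circadian clock (7 rose and 8 fell of 19, camera adjusted p = 0.809). Also short of the threshold were autophagy and lysosome (10 rose and 7 fell of 28, camera adjusted p = 0.451), GABA receptors (4 rose and 5 fell of 17, camera adjusted p = 0.809) and hormone and peptide receptors (9 rose and 10 fell of 27, camera adjusted p = 0.813). Further ones were interferon response (7 rose and 5 fell of 23, camera adjusted p = 0.598) and the NuRD and PAF1 chromatin and elongation complexes (3 rose and 11 fell of 20, camera adjusted p = 0.475). The last were potassium channels (10 rose and 17 fell of 45, camera adjusted p = 0.451), ribosome biogenesis (13 rose and 9 fell of 35, camera adjusted p = 0.39) and synaptic vesicle release (5 rose and 13 fell of 29, camera adjusted p = 0.26). The circadian list had a median of -0.064 and a mean of 0.14, so its signs differed. None of the 8 lists of markers of other cell types passed camera in wild type. They were astrocytes (2 rose and 0 fell of 8, camera adjusted p = 0.432), dopamine neurons (1 rose and 1 fell of 5, camera adjusted p = 0.877), endothelial cells (2 rose and 0 fell of 4, camera adjusted p = 0.768) and mural cells and fibroblasts (0 rose and 1 fell of 3, camera adjusted p = 0.701). The rest were oligodendrocytes (0 rose and 3 fell of 4, camera adjusted p = 0.175), other hypothalamic neurons (4 rose and 0 fell of 6, camera adjusted p = 0.152), Pomc neurons (0 rose and 1 fell of 3, camera adjusted p = 0.769) and tanycytes and ependyma (2 rose and 0 fell of 6, camera adjusted p = 0.813). Single markers did change, as the oligodendrocyte gene Cnp fell (-1.34 ± 0.15, edgeR adjusted p = 8.68e-09) and the peptide gene Gal, listed for other hypothalamic neurons, rose (1.58 ± 0.17, edgeR adjusted p = 4.13e-09). The mean log2 CPM of the oligodendrocyte list went from 4.14 ± 0.19 to 3.34 ± 0.13 in wild type (exact permutation p = 0.00794, adjusted p = 0.0125) and from 4.31 ± 0.25 to 3.34 ± 0.086 in cKO (mean ± SD, n = 5, adjusted p = 0.0114). That of the mural cell and fibroblast list fell from 0.82 ± 0.20 to -0.15 ± 0.57 in wild type (exact permutation adjusted p = 0.0125) and from 1.27 ± 0.36 to -0.054 ± 0.61 in cKO (0.0218), and that of the endothelial list rose from 0.76 ± 0.46 to 1.76 ± 0.36 in wild type (0.0228), where cKO had 1.39 and 1.29 (0.762).

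Fasting of cKO neurons asks which of these changes occurred with Phf6 reduced. Agrp rose 2.23-fold (log2 fold change 1.16 ± 0.086 SE, 5 against 5 libraries, edgeR adjusted p = 9.44e-12) and Npy rose 1.93-fold (0.95 ± 0.093, edgeR adjusted p = 1.48e-09). Cdkn1a rose 7.66-fold from 44.5 ± 1.97 to 341 ± 53.1 CPM (2.94 ± 0.093, edgeR adjusted p = 3.29e-19). The metallothioneins Mt1 (2.18 ± 0.15, edgeR adjusted p = 3.45e-12) and Mt2 (2.46 ± 0.21, edgeR adjusted p = 1.37e-10), the glucocorticoid target Fkbp5 (1.84 ± 0.12, edgeR adjusted p = 7.98e-13) and the receptor gene Tnfrsf12a (2.8 ± 0.13, edgeR adjusted p = 2.03e-15) rose. The activity gene Fosb rose (3.25 ± 0.34, edgeR adjusted p = 3.95e-09), and Dusp1, which encodes a MAP kinase phosphatase, fell (-1.49 ± 0.15, edgeR adjusted p = 1.92e-09). Large falls included Bhlhe40 (-3.45 ± 0.18, edgeR adjusted p = 8.45e-15), the phospholipase gene Plch1 (-3.06 ± 0.25, edgeR adjusted p = 6.49e-11) and Mef2c (-2.74 ± 0.23, edgeR adjusted p = 1.37e-10). Socs3 (-2.73 ± 0.33, edgeR adjusted p = 5.58e-08) and the clock-output gene Dbp (-2.37 ± 0.16, edgeR adjusted p = 8.12e-13) fell too, and Dbp shares 18% of its exon bases with Sphk2 on the opposite strand. Ghsr rose (1.02 ± 0.10, edgeR adjusted p = 3.68e-09) and Npy2r fell from 390 ± 8.5 to 127 ± 11.6 CPM (-1.62 ± 0.079, edgeR adjusted p = 2.71e-15). The lipid-carrier gene Apoe rose (3.24 ± 0.86, edgeR adjusted p = 0.00231) with a wide spread, at 39.3 ± 31.9 CPM in fasted cKO. In all, 3445 genes rose and 3579 fell, 572 and 833 of them by at least 2-fold, and the balance depended on scaling, with 3208 and 3909 under upper-quartile normalization and 3673 and 2971 with GC and length offsets.

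In cKO as in wild type 15 of 33 lists passed camera with fasting, 9 upward and 6 downward, and 11 passed with an estimated correlation. Of the cytosolic ribosomal protein genes, 76 of 78 rose, 0 fell and 2 did not pass (76 and 0 adjusted over the list alone), with Rpl10 (0.9 ± 0.055) as an example. Their median was 0.71 (camera adjusted p = 5.06e-46, adjusted p = 0.046 with an estimated correlation). Of the nuclear oxidative phosphorylation genes, 60 of 72 rose, 6 fell and 6 did not pass (60 and 6 adjusted over the list alone), such as Ndufa1 (0.84 ± 0.061), which with GC and length offsets was at 0.12 (edgeR adjusted p = 0.0532). Their median was 0.47 (camera adjusted p = 1.21e-16, adjusted p = 0.101 with an estimated correlation), and 0.12 ± 0.041 with GC and length offsets. Of the proteasome genes, 28 of 33 rose, 1 fell and 4 did not pass (28 and 1 adjusted over the list alone), among them Psmb3 (0.95 ± 0.049). Their median was 0.53 (camera adjusted p = 6.28e-15, adjusted p = 0.0261 with an estimated correlation). Of the endoplasmic reticulum stress and folding genes, 29 of 38 rose, 0 fell and 9 did not pass (29 and 1 adjusted over the list alone), including Dnajb9 (1.34 ± 0.058) and the secreted folding factor Manf (1.54 ± 0.092). Their median was 0.58 (camera adjusted p = 5.27e-14, adjusted p = 0.000997 with an estimated correlation). Of the ribosome biogenesis genes, 18 of 35 rose, 3 fell and 14 did not pass (19 and 3 adjusted over the list alone), such as the nucleolar genes Gnl3 (1.3 ± 0.083) and Npm1 (0.75 ± 0.046). Their median was 0.26 (camera adjusted p = 0.00317, adjusted p = 0.0404 with an estimated correlation). Of the peptide processing and secretory granule genes, 12 of 20 rose, 5 fell and 3 did not pass (12 and 5 adjusted over the list alone), with Vgf (1.78 ± 0.079) and Scg2 (0.99 ± 0.070). Their median was 0.27 (camera adjusted p = 0.000977, adjusted p = 0.0375 with an estimated correlation). Of the glucocorticoid and FoxO response genes, 11 of 24 rose, 4 fell and 9 did not pass (11 and 4 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 0.000569, adjusted p = 0.046 with an estimated correlation). Of the late activity genes, 11 of 17 rose, 1 fell and 5 did not pass (12 and 1 adjusted over the list alone). Their median was 0.83 (camera adjusted p = 9.68e-05, adjusted p = 0.0171 with an estimated correlation). Of the immediate early and activity genes, 11 of 34 rose, 8 fell and 15 did not pass (12 and 8 adjusted over the list alone), so this list did not pass in cKO. Their median was 0.22 (camera adjusted p = 0.681, adjusted p = 0.748 with an estimated correlation).

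Downward with fasting in cKO 6 lists passed. Of the cholesterol synthesis genes, 2 of 24 rose, 19 fell and 3 did not pass (3 and 19 adjusted over the list alone), including Hmgcs1 (-0.99 ± 0.093) and the pathway's regulator Srebf2 (-1.64 ± 0.12). Their median was -0.84 (camera adjusted p = 4.05e-06, adjusted p = 0.0261 with an estimated correlation). Of the circadian clock genes, 4 of 19 rose, 9 fell and 6 did not pass (4 and 9 adjusted over the list alone), with the repressor gene Nr1d1 (-1.32 ± 0.12) among them, and on voom values the list did not pass (camera adjusted p = 0.0814). Their median was -0.4 (camera adjusted p = 0.0124, adjusted p = 0.0375 with an estimated correlation). Of the ionotropic glutamate receptor and scaffold genes, 4 of 38 rose, 22 fell and 12 did not pass (4 and 22 adjusted over the list alone), such as the scaffold Shank1 (-1.39 ± 0.12) and the kinase Camk2a (-1.13 ± 0.10). Their median was -0.41 (camera adjusted p = 0.000307, adjusted p = 0.0171 with an estimated correlation). Of the sodium, calcium and HCN channel genes, 2 of 28 rose, 14 fell and 12 did not pass (2 and 15 adjusted over the list alone), including Scn9a (-0.87 ± 0.071). Their median was -0.4 (camera adjusted p = 0.00139, adjusted p = 0.046 with an estimated correlation). Of the cytokine and insulin feedback genes, 4 of 27 rose, 15 fell and 8 did not pass (4 and 15 adjusted over the list alone). Their median was -0.35 (camera adjusted p = 0.0124, adjusted p = 0.0622 with an estimated correlation). Of the glycolysis genes, 0 of 20 rose, 8 fell and 12 did not pass (0 and 8 adjusted over the list alone). Their median was -0.082 (camera adjusted p = 0.00869, adjusted p = 0.344 with an estimated correlation). With fasted replicates 1 and 2 alone the clock list (camera adjusted p = 0.0698) and the cytokine list (0.0718) did not pass. Heat shock genes did not pass as a list (5 rose and 6 fell of 19, camera adjusted p = 0.229), nor did AgRP neuron identity genes (8 rose and 2 fell of 14, camera adjusted p = 0.113).

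Markers of other hypothalamic neurons were higher with fasting in both genotypes, and their list passed in cKO alone. Their mean went from 1.45 ± 0.13 to 2.83 ± 0.20 log2 CPM in wild type (mean ± SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0125) and from 1.65 ± 0.26 to 2.95 ± 0.50 in cKO (exact permutation p = 0.00794, adjusted p = 0.0114). In each genotype 4 of 6 rose and 0 fell, with a median of 1.87 in wild type (camera adjusted p = 0.152) and 1.72 in cKO (camera adjusted p = 0.0349, adjusted p = 0.101 with an estimated correlation, 4 and 0 adjusted over the list alone). In cKO the list did not pass with fasted replicates 1 and 2 alone (camera adjusted p = 0.26), with GC and length offsets (0.0734), without any 1 of the fasted wild-type libraries (replicates 1 to 5, camera adjusted p = 0.0684, 0.0564, 0.0586, 0.059 and 0.0582), or without cKO_fasted replicate 3 (0.0744), 4 (0.0691) or 5 (0.0553). Pomc, the peptide gene of neighbouring satiety neurons, rose (2.11 ± 0.44, edgeR adjusted p = 0.000217) with a large spread. It was at 35.5 and 41.1 CPM in cKO_fasted replicates 1 and 2 and at 194, 442 and 337 CPM in replicates 3, 4 and 5. With fasted replicates 1 and 2 alone the Pomc change was -0.35 (edgeR adjusted p = 0.175), so its rise rests on the other 3 fasted cKO libraries. Tanycyte and ependymal markers went from -0.66 ± 0.12 to 0.82 ± 0.71 mean log2 CPM (mean ± SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0114), but camera did not pass (4 rose and 0 fell of 6, camera adjusted p = 0.229). Of the 15 markers written for other hypothalamic neurons, 6 passed the count filter. The sort for tdTomato would remove cells of these types, and the labels give no measure of its purity.

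Most fasting changes had the same direction in both genotypes. Of the genes called in each, 2644 rose in both where 1020 would if calls were independent, 2671 fell in both where 1119 would, and 52 and 101 went opposite ways. Across the 13237 genes the fasting log2 fold changes of the genotypes, which share no libraries, had r = 0.752 and rho = 0.746, and genes are not independent replicates. Over the 8974 genes changed by fasting on average, the fitted slope of the cKO change against the wild-type change was 0.69, and 62.7% of these genes had a smaller change in cKO. The slope was 0.81 with fasted replicates 1 and 2 alone and 0.622 with replicates 3 to 5 alone. The genes with the smallest p-values for the average included Cdkn1a (4.54 ± 0.076, edgeR adjusted p = 6.68e-27), the actin-linked gene Fam107b (3.08 ± 0.077, edgeR adjusted p = 2.45e-22) and Lxn, a carboxypeptidase inhibitor gene (1.68 ± 0.043, edgeR adjusted p = 2.73e-22). In all, 4290 genes rose and 4684 fell on average (4551 and 4170 with GC and length offsets), and 16 lists passed, 9 of them with an estimated correlation.

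**Figure D3:**
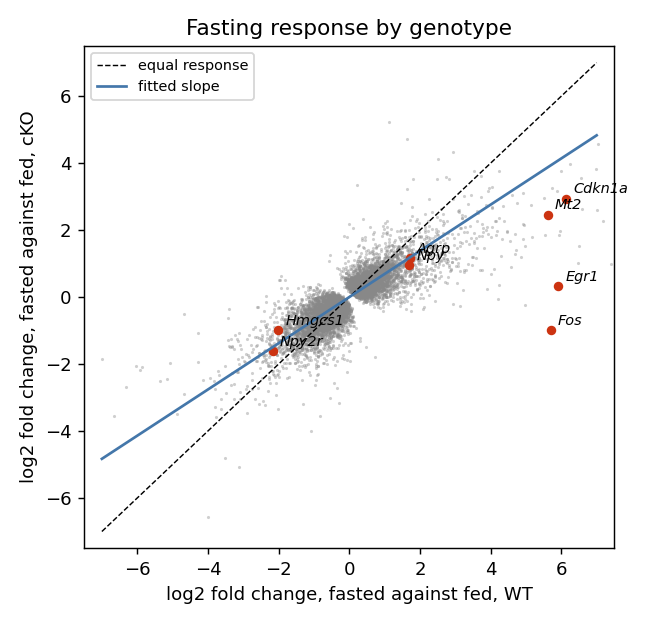
Fasting log2 fold change in cKO against that in wild type for the 8974 genes changed by fasting on average, with 1 point per gene, the fitted slope of 0.69 and the line of equal change.

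The cKO comparison in fed mice asks what loss of Phf6 changes without a fast. Of the 777 genes that rose, 600 also rose with fasting in wild type, a comparison read against the same fed wild-type libraries. Fos rose 41.4-fold from 2.91 ± 0.712 to 120 ± 7.39 CPM (log2 fold change 5.37 ± 0.14 SE, n = 5 against 5, edgeR adjusted p = 1.79e-21). Egr1 (45.1-fold, 5.5 ± 0.21, edgeR adjusted p = 1.28e-17), Nr4a1 (4.74 ± 0.30, edgeR adjusted p = 4.25e-12), Junb (1.19 ± 0.10, edgeR adjusted p = 1.29e-09) and the activity-induced kinase gene Plk2 (1.78 ± 0.15, edgeR adjusted p = 9.32e-10) rose too. Cdkn1a rose from 4.45 ± 0.686 to 44.5 ± 1.97 CPM (3.31 ± 0.12, edgeR adjusted p = 2.79e-18). Mt1 (2.84 ± 0.17, edgeR adjusted p = 1.29e-12), Mt2 (2.99 ± 0.28, edgeR adjusted p = 8.48e-09) and Nts (4.998 ± 0.70, edgeR adjusted p = 1.31e-05) rose. Npy rose 1.41-fold (0.49 ± 0.092, edgeR adjusted p = 0.000537), and Agrp did not pass (0.15 ± 0.085, edgeR adjusted p = 0.288) in the fit of all libraries, though it passed with the fed groups alone (0.15, edgeR adjusted p = 0.0026). Falls besides Phf6 included Gnb3, a G-protein subunit gene (-1.36 ± 0.16, edgeR adjusted p = 6.19e-07), and the oxidase subunit gene Cyba (-1.19 ± 0.21, edgeR adjusted p = 0.00034). The dopamine-synthesis gene Th (-1.47 ± 0.24, edgeR adjusted p = 7.92e-05) and the cyclin gene Ccnd2 (-1.48 ± 0.14, edgeR adjusted p = 8.85e-09) fell as well. Serpina3h fell from 31.5 ± 4.25 to 6.38 ± 0.791 CPM (-2.3 ± 0.15, edgeR adjusted p = 1.01e-11), but it is annotated as a pseudogene of a family with near-identical copies, so the locus is uncertain. In all, 777 genes rose and 504 fell, 162 and 53 of them by at least 2-fold, and the counts were 684 and 763 with GC and length offsets.

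In fed mice 8 of 33 lists passed, 6 upward and 2 downward, and 6 passed with an estimated correlation. Of the immediate early and activity genes, 20 of 34 rose, 1 fell and 13 did not pass (23 and 2 adjusted over the list alone). Their median was 1.31 (camera adjusted p = 8.54e-48, adjusted p = 3.4e-08 with an estimated correlation). Of the glucocorticoid and FoxO response genes, 14 of 24 rose, 0 fell and 10 did not pass (17 and 0 adjusted over the list alone), with Sgk1 rising from 44.3 ± 2.98 to 166 ± 7.74 CPM (1.91 ± 0.074). Their median was 0.55 (camera adjusted p = 7.64e-40, adjusted p = 1.07e-06 with an estimated correlation). Of the late activity genes, 6 of 17 rose, 1 fell and 10 did not pass (10 and 1 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 5.6e-08, adjusted p = 0.00106 with an estimated correlation). Of the peptide processing and secretory granule genes, 9 of 20 rose, 0 fell and 11 did not pass (12 and 1 adjusted over the list alone), including Vgf (0.68 ± 0.079), Chga (0.54 ± 0.079) and Scg2 (0.41 ± 0.070). Their median was 0.23 (camera adjusted p = 2.52e-05, adjusted p = 0.0106 with an estimated correlation). Of the AgRP neuron identity genes, 6 of 14 rose, 0 fell and 8 did not pass (6 and 0 adjusted over the list alone), among them Lepr (0.94 ± 0.14) and Ghsr (0.63 ± 0.11). Their median was 0.23 (camera adjusted p = 0.00303, adjusted p = 0.0172 with an estimated correlation). Of the circadian clock genes, 6 of 19 rose, 1 fell and 12 did not pass (7 and 1 adjusted over the list alone), including Per1 (1.16 ± 0.15), Per2 (1.06 ± 0.21) and Nfil3 (1.17 ± 0.11). Their median was 0.29 (camera adjusted p = 0.00308, adjusted p = 0.0127 with an estimated correlation), and 0.16 on the deposited normalized values. Of the heat shock genes, 0 of 19 rose, 9 fell and 10 did not pass (1 and 10 adjusted over the list alone), with Hsph1 (-0.33 ± 0.073) and Chordc1 (-0.56 ± 0.13) lower. Their median was -0.16 (camera adjusted p = 0.000107, adjusted p = 0.0704 with an estimated correlation). Of the ribosome biogenesis genes, 0 of 35 rose, 5 fell and 30 did not pass (0 and 8 adjusted over the list alone), and both Ubtf (-0.69 ± 0.10) and Polr1e (-0.62 ± 0.099), which serve ribosomal RNA transcription, fell. Their median was -0.035 (camera adjusted p = 0.017, adjusted p = 0.0843 with an estimated correlation). Ribosomal protein genes (0 rose and 0 fell of 78, camera adjusted p = 0.824), oxidative phosphorylation genes (1 rose and 0 fell of 72, camera adjusted p = 0.061) and cholesterol synthesis genes (0 rose and 1 fell of 24, camera adjusted p = 0.824) did not pass.

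Marker lists of other cell types did not pass camera between the fed genotypes, but the tanycyte and ependymal list scores differed. The astrocyte list had 1 rise in 8, Agt, which encodes angiotensinogen (2.76 ± 0.25, edgeR adjusted p = 5.1e-09), and the endothelial list had the highest median, 0.75, with none of 4 called. The tanycyte list had a median of -1.27 with 1 of 6 lower, and its mean went from 0.18 ± 0.73 log2 CPM in wild type to -0.66 ± 0.12 in cKO (mean ± SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0202). Without cKO_fed replicate 2, 905 genes passed.

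The cKO comparison in fasted mice asks what loss of Phf6 changes under hunger. Agrp was 1.32-fold lower in cKO (log2 fold change -0.4 ± 0.085 SE, n = 5 against 5, edgeR adjusted p = 0.00144). Npy did not pass (-0.25 ± 0.092, edgeR adjusted p = 0.0508), though it passed without WT_fasted replicate 3 (-0.30, edgeR adjusted p = 0.0289), 4 (-0.30, 0.0269) or 5 (-0.31, 0.0182), or without cKO_fasted replicate 1 (-0.28, 0.0433) or 2 (-0.33, 0.0129). Npy also passed with a term for the library sets (-0.25, edgeR adjusted p = 2.89e-05), with fasted replicates 1 and 2 alone (-0.33, 2.22e-05) and with replicates 3 to 5 alone (-0.18, 0.000763), fits chosen after seeing the data. Fos was lower, at 60.9 ± 11.5 against 151 ± 14.4 CPM (-1.31 ± 0.11, edgeR adjusted p = 3.22e-09). Jun (0.83 ± 0.094, edgeR adjusted p = 7.83e-07), Nr4a3 (1.81 ± 0.25, edgeR adjusted p = 1.32e-05) and the stress factor gene Atf3 (2.57 ± 0.30, edgeR adjusted p = 1.13e-06) were higher. The orexin receptor gene Hcrtr1 (-1.54 ± 0.27, edgeR adjusted p = 0.000223) and Mchr1, for melanin-concentrating hormone (-1.35 ± 0.19, edgeR adjusted p = 1.52e-05), were lower. Gnb3 (-1.71 ± 0.17, edgeR adjusted p = 1.06e-07), Cyba (-1.8 ± 0.22, edgeR adjusted p = 2.47e-06) and the uncertain locus Serpina3h (-1.94 ± 0.16, edgeR adjusted p = 3.22e-09) were lower as in fed mice. Cartpt, a satiety peptide gene (0.67 ± 0.11, edgeR adjusted p = 8.46e-05), Nudt12, which encodes an NADH hydrolase (1.95 ± 0.39, edgeR adjusted p = 0.000865), and the folding factor gene Creld2 (1.15 ± 0.11, edgeR adjusted p = 7.99e-08) were higher. Pomc was higher (1.46 ± 0.44, edgeR adjusted p = 0.018) but did not pass without cKO_fasted replicate 4 (0.99, edgeR adjusted p = 0.101) or 5 (1.22, 0.0594), and with fasted replicates 1 and 2 alone it was at -0.18 (0.705). With those replicates alone Nudt12 (1.09, edgeR adjusted p = 0.064) and Cartpt (0.28, 0.121) also did not pass. In all, 1517 genes were higher and 1170 lower, 131 and 127 of them by at least 2-fold.

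In fasted mice 5 of 33 lists passed, 2 upward and 3 downward, and 2 passed with an estimated correlation. Of the heat shock genes, 9 of 19 rose, 0 fell and 10 did not pass (10 and 0 adjusted over the list alone), including Dnajb1 (0.61 ± 0.071), Chordc1 (1.02 ± 0.13) and Stip1 (0.35 ± 0.053). Their median was 0.32 (camera adjusted p = 1.11e-08, adjusted p = 0.0264 with an estimated correlation). Of the cholesterol synthesis genes, 10 of 24 rose, 1 fell and 13 did not pass (11 and 1 adjusted over the list alone), including Hmgcs1 (0.87 ± 0.099), Cyp51 (0.54 ± 0.083) and Sqle (0.61 ± 0.11). Their median was 0.2 (camera adjusted p = 0.000582, adjusted p = 0.228 with an estimated correlation). Of the cytosolic ribosomal protein genes, 0 of 78 rose, 35 fell and 43 did not pass (0 and 42 adjusted over the list alone), such as Rps2 (-0.29 ± 0.047) and Rpl3 (-0.33 ± 0.053). Their median was -0.17 (camera adjusted p = 1.74e-12, adjusted p = 0.725 with an estimated correlation). Of the circadian clock genes, 2 of 19 rose, 7 fell and 10 did not pass (3 and 12 adjusted over the list alone), among them Nr1d1 (-1.002 ± 0.13), Per2 (-1.09 ± 0.21) and Cry2 (-0.56 ± 0.12). Their median was -0.39 (camera adjusted p = 0.0033, adjusted p = 0.0264 with an estimated correlation). With fasted replicates 1 and 2 alone Per2 (-0.91, edgeR adjusted p = 0.0502) and Cry2 (-0.40, 0.125) did not pass, nor did the clock list (camera adjusted p = 0.0623) or the cholesterol list (0.359). Of the glucocorticoid and FoxO response genes, 1 of 24 rose, 6 fell and 17 did not pass (3 and 9 adjusted over the list alone), with Gadd45a (-0.93 ± 0.13) and Nfkbia (-0.64 ± 0.11) lower, though Gadd45a is uncertain because it shares 19.1% of its exon bases with an opposite-strand transcript. Their median was -0.21 (camera adjusted p = 0.0357, adjusted p = 0.511 with an estimated correlation). That list did not pass without WT_fasted replicate 1 (camera adjusted p = 0.141) or 2 (0.0791), or without cKO_fasted replicate 3 (0.0768), 4 (0.101) or 5 (0.1), nor with fasted replicates 1 and 2 alone (0.359) with replicates 3 to 5 alone (0.0523) or with GC and length offsets (0.05). Endoplasmic reticulum stress genes (8 rose and 2 fell of 38, camera adjusted p = 0.0564) and immediate early and activity genes (8 rose and 4 fell of 34, camera adjusted p = 0.553) did not pass. The counts depended on scaling, with 1232 higher and 1575 lower under upper-quartile normalization.

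The cKO effects of fed and fasted mice had little in common across genes. Their log2 fold changes, which share no libraries, had r = 0 and rho = -0.033 over 13237 genes, and genes are not independent replicates. Of the called genes 115 rose in both where 89 would if calls were independent, and 62 fell in both where 44.5 would. In opposite directions, 101 rose in fed and fell in fasted mice where 68.7 would, and 121 fell in fed and rose in fasted mice where 57.8 would. On average over both states, 1144 genes rose and 700 fell, but 993 and 887 did under upper-quartile normalization and 1031 and 957 with GC and length offsets. Phf6 (-1.52 ± 0.052, edgeR adjusted p = 2.03e-18), Serpina3h (-2.12 ± 0.11, edgeR adjusted p = 2.54e-14) and the transcriptional regulator gene Cited2 (0.82 ± 0.060, edgeR adjusted p = 1e-10) had among the smallest p-values. For this average 5 lists passed, 3 of them with an estimated correlation.

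**Figure D4:**
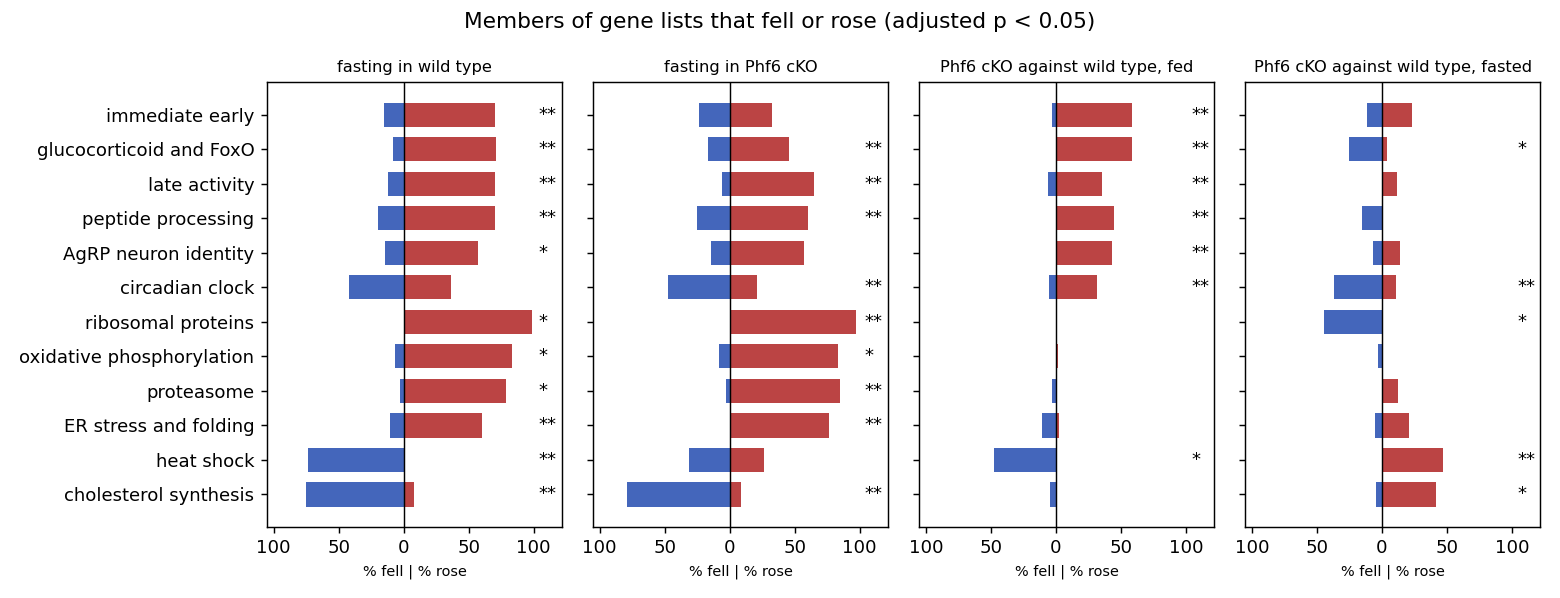
Percent of tested members that fell or rose, drawn to the left and right of 0, for 12 gene lists in the 4 comparisons, where 1 asterisk marks lists that passed camera with the preset correlation alone and a pair marks lists that also passed with an estimated correlation. Ribosomal protein genes rose with fasting in both genotypes, and immediate early and activity genes rose with fasting in wild type and with cKO in fed mice.

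The interaction asks whether fasting changed a gene by a different amount in cKO than in wild type. Fos had the smallest p-value, with a cKO response minus wild-type response of -6.68 ± 0.18 (log2 ± SE, 20 libraries, edgeR adjusted p = 3.72e-21). It went from 2.91 ± 0.712 to 151 ± 14.4 CPM with fasting in wild type and from 120 ± 7.39 to 60.9 ± 11.5 CPM in cKO. Egr1 (-5.59 ± 0.26, edgeR adjusted p = 3.21e-15) went from 0.805 ± 0.443 to 48 ± 7.7 CPM in wild type and from 35.9 ± 7.22 to 45 ± 5.19 CPM in cKO. Nr4a1 (-5.2 ± 0.38, edgeR adjusted p = 1.88e-10), Cdkn1a (-3.2 ± 0.15, edgeR adjusted p = 2.28e-15) and Sgk1 (-2.06 ± 0.10, edgeR adjusted p = 6.74e-15) also had a more negative response in cKO. So did the metallothioneins Mt1 (-2.73 ± 0.23, edgeR adjusted p = 2.04e-09) and Mt2 (-3.15 ± 0.34, edgeR adjusted p = 3.31e-07). Agrp (-0.55 ± 0.12, edgeR adjusted p = 0.0019), Npy (-0.75 ± 0.13, edgeR adjusted p = 0.000194) and Lepr (-0.92 ± 0.19, edgeR adjusted p = 0.00114) rose less in cKO. Phf6 fell less in cKO (0.9 ± 0.10, edgeR adjusted p = 6.4e-07). More positive responses in cKO included Kpna2, a nuclear import gene that went from 107 ± 8.71 to 73.8 ± 9.44 CPM in wild type and from 49.4 ± 2.36 to 119 ± 19.8 CPM in cKO (1.8 ± 0.13, edgeR adjusted p = 1.98e-10). Creld2 was another (1.65 ± 0.15, edgeR adjusted p = 2.33e-08). In all, 1174 genes had a more positive and 1117 a more negative response in cKO, and the balance depended on scaling, with 990 and 1366 under upper-quartile normalization and 1377 and 1029 with GC and length offsets.

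The interaction subtracts the wild-type response, so it shares libraries with both fasting comparisons, and a more negative response goes with a rise in wild type partly by construction. Of the 1117 more negative genes, 444 rose in both genotypes, 397 rose in wild type and were not called in cKO, 172 were called in cKO alone as falls, 52 rose in wild type and fell in cKO, 40 fell in both and 12 were called in neither. Of the 1174 more positive genes, 440 fell in wild type and were not called in cKO, 288 fell in both, 251 were called in cKO alone as rises, 101 fell in wild type and rose in cKO, 84 rose in both and 10 were called in neither. The group farthest from the other 3 was fed wild type for 422 of the more negative genes, fasted wild type for 446, fed cKO for 74 and fasted cKO for 175. For the more positive genes these counts were 171, 626, 117 and 260.

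For the interaction 12 of 33 lists passed, 5 upward and 7 downward, and 5 passed with an estimated correlation. Of the glucocorticoid and FoxO response genes, 0 of 24 rose, 15 fell and 9 did not pass (0 and 18 adjusted over the list alone). Their median was -0.88 (camera adjusted p = 8.79e-28, adjusted p = 1.03e-05 with an estimated correlation). Of the immediate early and activity genes, 2 of 34 rose, 14 fell and 18 did not pass (2 and 17 adjusted over the list alone), with Dusp1 (-1.97 ± 0.21) among the more negative. Their median was -1.09 (camera adjusted p = 4.77e-21, adjusted p = 1.03e-05 with an estimated correlation). Of the circadian clock genes, 1 of 19 rose, 9 fell and 9 did not pass (1 and 10 adjusted over the list alone), including Per1 (-1.51 ± 0.21), Per2 (-2.15 ± 0.30) and Cry2 (-1.15 ± 0.17). Their median was -0.56 (camera adjusted p = 5.87e-06, adjusted p = 0.000729 with an estimated correlation). Of the peptide processing and secretory granule genes, 0 of 20 rose, 10 fell and 10 did not pass (1 and 11 adjusted over the list alone), such as Vgf (-0.6 ± 0.11), Pcsk2 (-0.6 ± 0.11) and Scg3 (-0.34 ± 0.072). Their median was -0.28 (camera adjusted p = 0.000147, adjusted p = 0.0199 with an estimated correlation). Of the late activity genes, 1 of 17 rose, 7 fell and 9 did not pass (2 and 7 adjusted over the list alone). Their median was -0.43 (camera adjusted p = 0.00491, adjusted p = 0.057 with an estimated correlation). Of the heat shock genes, 14 of 19 rose, 0 fell and 5 did not pass (14 and 0 adjusted over the list alone), including Chordc1 (1.58 ± 0.18) and Hsph1 (0.8 ± 0.10). Their median was 0.49 (camera adjusted p = 4.71e-12, adjusted p = 0.00307 with an estimated correlation). Of the cholesterol synthesis genes, 7 of 24 rose, 0 fell and 17 did not pass (9 and 1 adjusted over the list alone), with Hmgcs1 (1.02 ± 0.13) among them. Their median was 0.25 (camera adjusted p = 0.00491, adjusted p = 0.22 with an estimated correlation), and with fasted replicates 1 and 2 alone the list did not pass (camera adjusted p = 0.277). In these counts rose and fell mean a more positive and a more negative response in cKO.

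The other 5 lists that passed for the interaction had small medians. Of the cytosolic ribosomal protein genes, 0 of 78 rose, 19 fell and 59 did not pass (0 and 27 adjusted over the list alone), and with GC and length offsets the list did not pass (camera adjusted p = 0.0678). Their median was -0.17 (camera adjusted p = 3.86e-06, adjusted p = 0.661 with an estimated correlation). Of the oxidative phosphorylation genes, 0 of 72 rose, 1 fell and 71 did not pass (0 and 1 adjusted over the list alone), and the list did not pass without WT_fasted replicate 1 (camera adjusted p = 0.0543), without cKO_fasted replicate 1 (0.051) or with GC and length offsets (0.931). Their median was -0.1 (camera adjusted p = 0.0125, adjusted p = 0.71 with an estimated correlation). Of the endoplasmic reticulum stress genes, 8 of 38 rose, 2 fell and 28 did not pass (8 and 2 adjusted over the list alone), which did not pass without WT_fasted replicate 2 (camera adjusted p = 0.0597) or cKO_fasted replicate 5 (0.0517). Their median was 0.12 (camera adjusted p = 0.0229, adjusted p = 0.221 with an estimated correlation). Of the NuRD and PAF1 complex genes, 5 of 20 rose, 0 fell and 15 did not pass (5 and 0 adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.0211, adjusted p = 0.243 with an estimated correlation). Of the ribosome biogenesis genes, 11 of 35 rose, 2 fell and 22 did not pass (13 and 3 adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.024, adjusted p = 0.153 with an estimated correlation). With fasted replicates 3 to 5 alone the endoplasmic reticulum stress (camera adjusted p = 0.0828), NuRD and PAF1 (0.128) and ribosome biogenesis (0.212) lists did not pass. AgRP neuron identity genes did not pass (1 rose and 4 fell of 14, camera adjusted p = 0.0969).

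The genotype calls rest on treating the 20 libraries as independent samples. When the counts of each apparent set of libraries were summed, to 6 libraries, an alternative chosen after seeing the data, edgeR called 2564 genes for fasting in wild type and 996 in cKO. It then called 8 genes for cKO in fed mice, 6 for the interaction and 0 for cKO in fasted mice, where 313, 610 and 1259 genes had an unadjusted p under 0.05. In that fit each fed group was 1 sum, assumed to vary like the fasted sums.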

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

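The tests of heat shock genes, of other cell types, of library sets and of cKO cells in wild-type samples were chosen after the results were seen, as were the GC and length offsets, and the predictions for depth and for GC and length were written before their tests.

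A library lay far from the others of its group. Agrp was at 4370 CPM in cKO_fed replicate 1, and its gap to the nearest of the other 4 libraries passed the critical share of 0.71 of the group's range. In 32 groups of 5 that were checked this way, chance alone would mark about 1 in 20.

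The fasting response differed between genotypes by the interaction test for these genes (log2, cKO minus wild type, edgeR). It was more negative in cKO for Fos (-6.68), Egr1 (-5.59), Nr4a1 (-5.20), Cdkn1a (-3.20), Mt2 (-3.15), Mt1 (-2.73), Per2 (-2.15), Sgk1 (-2.06), Dusp1 (-1.97), Per1 (-1.51), Cry2 (-1.15), Lepr (-0.92), Npy (-0.75), Vgf (-0.60), Pcsk2 (-0.60), Agrp (-0.55) and Scg3 (-0.34). It was more positive for Kpna2 (1.80), Creld2 (1.65), Chordc1 (1.58), Hmgcs1 (1.02), Phf6 (0.90) and Hsph1 (0.80). List medians were more negative for immediate early and activity genes (-1.09), glucocorticoid and FoxO response (-0.88), circadian clock (-0.56), late activity genes (-0.43), peptide processing (-0.28), ribosomal proteins (-0.17) and oxidative phosphorylation (-0.10). They were more positive for heat shock (0.49), cholesterol synthesis (0.25), NuRD and PAF1 complexes (0.17), endoplasmic reticulum stress (0.12) and ribosome biogenesis (0.11). With an estimated correlation 5 of these 12 lists passed camera, namely immediate early and activity genes, glucocorticoid and FoxO response, circadian clock, peptide processing and heat shock. With GC and length offsets the ribosomal (camera adjusted p = 0.0678) and oxidative phosphorylation (0.931) lists did not pass.

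Activity-induced and glucocorticoid-responsive genes such as Fos and Sgk1 were lowest in fed wild-type libraries. Dissociation stress that raises chaperones along with activity genes is argued against, since the heat shock list was lower in fed cKO (median -0.16), although that list had an adjusted p = 0.0704 with an estimated correlation. RNA from oligodendrocytes or Pomc neurons is argued against. The higher of their marker medians was -0.067 ± 0.41 (SE), against 1.31 for the activity list and 2.01 for its 20 risen genes. RNA from the other 6 cell types tested stays open. Their markers averaged under 2 log2 CPM in fed wild type, near the floor. The 0.75 ± 0.76 of 4 endothelial genes cannot be told apart from 1.31 or 2.01. Collection time or handling cannot be told apart from genotype, as each fed group formed 1 set and the labels give no times. Clock list medians, 0.29 in fed and -0.39 in fasted cKO against wild type, leave timing open in both states. An effect of Phf6 loss on baseline activity is also open as a hypothesis.

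Ribosomal protein and oxidative phosphorylation genes were higher in fasted libraries of both genotypes. Their transcripts are short, with medians of 1076 and 1092 bases against 3424 for all tested genes, 96% of which had GC and length values. With GC and length offsets the highest adjusted p of both lists was 0.00341, but the medians shrank, for ribosomal genes from 0.87 to 0.52 ± 0.035 in wild type and 0.71 to 0.48 ± 0.027 in cKO, and for oxidative phosphorylation from 0.57 to 0.10 ± 0.046 and 0.47 to 0.12 ± 0.041. A length trend is therefore argued against as the whole cause, though it could account for most of the oxidative phosphorylation change. Lower counting depth by itself is argued against, since with all libraries thinned to 8494499 counts the lowest median was 0.48 ± 0.049. Thinning keeps each gene's share, so other differences that go with depth stay open. A response to fasting may remain, but with an estimated correlation, without offsets, the camera adjusted p was 0.0546 in wild type and 0.046 in cKO for the ribosomal list, and 0.0912 and 0.101 for oxidative phosphorylation.

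Phf6 was lower in fasted than in fed wild-type libraries. Lower depth stays open, since thinning (-1.12 ± 0.071) keeps each gene's share. Admixture of cKO cells would need 72.1% of the cells, and 20 genes lower in fed cKO and steady with fasting there changed by a median of -0.72 where admixture predicts -0.87, with a median difference of 0.12 ± 0.24 (SE) and 11 of 20 above the prediction. Serpina3h (0.087), Gnb3 (0.21) and Cyba (0.80) went against admixture, with -1.23, -0.84 and -0.75 predicted. The set cannot decide, as it was picked against the same fed wild-type libraries, which favours a fall. Regulation of Phf6 by feeding may explain the fall and was not tested otherwise.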

How the results depend on the processing

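The fits of fasted replicates 1 and 2 only, of fasted replicates 3 to 5 only, with a term for library sets, with summed sets and with GC and length offsets were chosen after seeing the data, and the other alternatives were planned. Where no cause is named, the cause was not tested.

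Counts of changed genes stayed within 1.5 times their value except in these fits. With summed sets, which leave 6 libraries, edgeR called 2564 genes for fasting in wild type, 996 in cKO, 8 for cKO in fed mice, 0 in fasted mice, 6 for the interaction, 4338 for average fasting and 12 for average cKO. The low counts follow in part from the few libraries. With only the groups compared 2952 genes passed for cKO in fed and 1352 in fasted mice, the reverse order. Limma-voom gave 2754 in fed mice, and fasted replicates 1 and 2 only gave 1682 in fasted mice. With fasted replicates 3 to 5 only, 3603 passed for the interaction and 3250 for average cKO. The DESeq2 test gave 8384, 7167, 1565, 2995 and 2607 genes for the 5 comparisons.

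Leaving out 1 library gave 7723 to 8164 genes for fasting in wild type, 6518 to 7176 in cKO, 905 to 1451 for cKO in fed mice, 2030 to 3193 in fasted mice, 1941 to 2700 for the interaction, 8793 to 8992 for average fasting and 1521 to 2285 for average cKO. Lists past the threshold numbered 15 to 16, 14 to 17, 8 to 9, 4 to 7 and 11 to 14 in the 5 comparisons. With a term for replicate number, a block that the labels do not name, the counts were 8090, 7069, 1318, 2785 and 2347 genes and 16, 16, 8, 6 and 15 lists. With an estimated correlation 7 lists passed for fasting in wild type, 2 for cKO in fasted mice and 5 for the interaction. Of 165 medians of passing lists under DESeq2 size factors, upper-quartile normalization and the deposited normalized values, 0 changed sign. The clock list in fed mice moved from 0.29 to 0.16 on the deposited normalized values, and under upper-quartile normalization the interaction medians moved from 0.12 to 0.078 for endoplasmic reticulum stress and from 0.11 to 0.071 for ribosome biogenesis.

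Phf6 kept its direction in every fit. Without 1 library its change ran from -1.15 to -1.08 for fasting in wild type, -0.27 to -0.16 in cKO, -1.997 to -1.94 for cKO in fed mice, -1.13 to -1.02 in fasted mice and 0.84 to 0.95 for the interaction. For fasting in cKO it did not pass with fasted replicates 3 to 5 only (-0.11, edgeR adjusted p = 0.196), with summed sets (-0.20, 0.492), or without cKO_fed replicate 1 (0.0593), cKO_fed replicate 4 (0.0541), cKO_fasted replicate 1 (0.0681) or cKO_fasted replicate 2 (0.0736). With summed sets it also did not pass for cKO in fasted mice (-1.10, edgeR adjusted p = 0.13) or the interaction (0.88, 0.881).

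The slope of the cKO against the wild-type response was 0.656 for genes changed by at least 2-fold, 0.81 with fasted replicates 1 and 2 only and 0.622 with fasted replicates 3 to 5 only. It ran from 0.666 to 0.721 without 1 library, the highest without cKO_fasted replicate 4. The share of the 10 most abundant genes differed by -1.27 points between fasted genotypes (exact permutation p = 0.143), where that of the 50 most abundant differed by -1.63 (exact permutation p = 0.0318, adjusted p = 0.0794).

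Pomc reversed with fasted replicates 1 and 2 only, to -0.35 for fasting in cKO (edgeR adjusted p = 0.175) and -0.18 for cKO in fasted mice (0.705). Its call in fasted mice was also lost with a robust fit (1.46, edgeR adjusted p = 0.0823), only the groups compared (1.45, 0.0864), limma-voom (1.13, 0.0675) and the deposited normalized values (0.94, 0.156). Npy in fasted cKO passed under upper-quartile normalization (-0.29, edgeR adjusted p = 0.0202), no filter (-0.25, 0.0306), a replicate term (-0.25, 0.0145) and the library-set fits already given. Of the 154 named pairs of gene and comparison, 83 stayed on their side of the threshold with summed sets and 71 did not.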

Other observations

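The comparison of genes shared between fasting in wild type and cKO in fed mice was chosen after the results were seen, and the counts over other splits of the libraries were planned.

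To test for chance, each count was ranked among 100 splits of the same libraries, the real one included. For changed genes 1 split, the real split, gave as many for fasting in wild type (7677 genes, highest other 0), fasting in cKO (7008, highest other 1), cKO in fed mice (2952, highest other 6) and cKO in fasted mice (1352, highest other 772), each fitted on its own 10 libraries. The split with 772 genes largely followed the sets, with replicates 1 and 2 of both genotypes on 1 side. With genotype permuted within feeding state, only the real split gave as many genes for the interaction (2291, highest other 715) and average cKO (1844, highest other 1106). Its slope was farthest from 1 on the log scale (0.69, others 0.774 to 1.31). As this removes every genotype effect, it cannot exclude chance for the interaction or slope alone. With feeding permuted within genotype, 1 split gave as many genes for average fasting (8974, highest other 3214).

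For gene lists only the real split gave as many for fasting in wild type (16 lists, highest other 14) and, with the same limit, for the interaction (12, highest other 9). Chance was not excluded by rank in the other comparisons, with 6 such splits for fasting in cKO (15 lists, highest other 16). For cKO they numbered 12 in fed mice (9 lists, highest other 12) and 30 in fasted mice (5, highest other 10).

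Fasting in wild type and cKO in fed mice share the fed wild-type libraries, so noise or a shift in these adds to any likeness. The covariance of their log2 fold changes across genes was 0.225, against 0.0272 in 10 simulations with no true change and 0.218 on average (0.214 to 0.224) in 10 splits of the fed wild-type libraries that gave each comparison its own controls. The correlations were 0.552, 0.497 and 0.454 (0.426 to 0.468 over the splits). With separate controls 481 genes rose in both on average (464 to 516), against 600 with shared controls and 0 in the simulations, and 341 fell in both (322 to 358), against 289. The likeness remained with separate controls, but these keep any shift of the whole group, and genes are not independent replicates.

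List scores per library passed exact permutation tests with an adjusted p under 0.05 for 23, 25, 15 and 0 of 33 lists in the first 4 comparisons. For cKO in fasted mice, where 0 passed, 6 lists had an unadjusted exact p under 0.05.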
